A study of Mus musculus with 1457 samples.

How the data were processed

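The series holds 1457 single cells of the AGM region of mouse embryos, each a GEO sample of its own. Cells were sorted by flow cytometry into single wells and polyA RNA was amplified by the Smart-seq2 method, per the labels' protocols. The values are counts of reads per gene and cell that the authors deposited in 2 tables without normalization, as the whole numbers and differing totals show. The tools bcl2fastq, STAR 2.4.2a, HTSeq 0.6.1p1 and R 3.6.2 and the genome build GRCm38 are named per the submitters' processing notes. The annotation release, the strand setting and any cell filter of the authors are not given in the sources used here. Without a stated strand setting, reads of a gene and of an antisense or overlapping partner cannot be told apart. Reads of near-identical copies, such as Hba-a1 and Hba-a2 or Hbb-bs and Hbb-bt, may have been dropped or split, so values of single globin genes are uncertain. Smart-seq2 reads carry no molecular identifiers, so PCR copies count as reads.

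The larger table had 1288 cells and the table of the ACE sorts 169. All columns were matched to a sample through its labels. The copy of the larger table used here ends within a row, so that 1 gene and the genes of later identifiers were not analysed here. Both tables were restricted to the 36131 genes held whole in both. This left out 13454 of the 49585 genes of the ACE table with 10.1% of its reads, of which Rn18s-rs5, a ribosomal RNA gene, took 9.20%. The 92 spike-in controls listed in the ACE table had 0 reads. Gene symbols are those the deposited tables pair with their Ensembl identifiers, and 10 genes that shared a symbol with another were kept apart by identifier. Chromosome positions are of GRCm38, from the GENCODE annotation.

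Groups followed the labels, as stage, sort gate, reporter line and genotype, which made 19 groups. Titles and stage fields disagreed for 126 cells, which were kept in groups of their own and out of the main comparisons. A further 277 cells were titled KO while their genotype field said heterozygous, and these are called titled KO. In 13 cells of the Runx1b endothelial sort the title was misspelt. No label named an embryo or litter, and cells of a group are not replicates, so each group counted as 1 sample. Cell types are sort gates; no cells were clustered or renamed. Single cells were sorted into wells, per the labels' protocols, and no doublet caller was run, so wells with more than 1 cell were not looked for. No cell was left out of the main values, since no filter was stated.

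Reads per cell ranged from 12 to 5652968 (median 598000). For the 13 comparisons of 1 sample against 1, reads were summed over the cells of a group and divided by that group's total per 1000000 reads (CPM). Sums have exact Poisson intervals, and shares of cells with at least 1 read have exact Clopper-Pearson intervals, both at 95%, which cover counting error only. For shares of 0 cells, and for the folds of Runx1 and Gfi1 over Endo, the limit that 3 cells or reads allow was given. Other values of 0 CPM stand without it. No p-value was computed for these comparisons. In log2 ratios a sum under 3 reads was set to 3 reads. A list member counted as measured with over 3 reads in either group. For 26 gene lists, the median log2 ratio of the measured members, where there were at least 5, was set against 10000 random lists of the same size drawn from 20 bins of mean expression. The percentile describes these sums of cells and is no test across embryos.

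Named genes followed a rule. In a comparison of 1 sample against 1, genes needed 20 CPM and reads in 25% of the cells of the higher group, and a difference of at least 2-fold by summed reads and by the mean of per-cell values. Of these, the 12 highest and 12 lowest by log2 ratio with 1 CPM added to both sides could be named. In the tested comparison, the 12 largest rises and falls past the threshold with the same sign in all 4 sets and at least 20 CPM in the higher sort were named. Mitochondrial, ribosomal protein, unnamed predicted, pseudogene and sex-linked marker genes were left out. The genes of the gates and targets, Runx1, Gfi1, Gfi1b, Ace, Kit, Cdh5, Itga2b and Ptprc, were always open to naming, and up to 4 members of each list with the largest differences. Some genes taken by the rule are not reported here.

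HE was tested against endothelium on 8 sums of cells, the endothelial and the HE sort of 4 sort sets (Gfi1/Gfi1b heterozygous at E10.5 and at E11.5, Runx1b heterozygous, ACE sorts), with 1.46e+07 to 1.57e+08 reads each. The sets differ in genotype or stage and so in embryos, but nothing in the labels states how many embryos each holds, so p-values of single genes measure the spread between these sets. edgeR 4.0.16 in R 4.3.3 was used with filterByExpr, which left out 21578 genes, TMM scaling, the sort set as a block (3 residual degrees of freedom), the quasi-likelihood F-test and Benjamini-Hochberg adjustment over 14553 genes at a threshold of 0.05. The pairing of the sorts of a set comes from the labels (line and stage, or the ACE sorts). Deviations from the mean of each gate correlated within each set (0.132, 0.165, 0.172 and 0.380 across genes) and by −0.233 to 0.0872 between sorts of different sets. These values cannot tell shared embryos from a shared line, stage or table, and centering ties those between sets to those within. Reads of Xist, expressed in female cells, were found in 43.75% of Endo and 5% of HE cells at E11.5. In the Runx1b line the shares were 54.7% and 81.3%, so these paired sorts differed in embryo make-up. Lists with enough measured members, 24 in all, were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, and again with an estimated correlation. With the preset correlation camera weighs the genes of a list against all other genes, so its p-values do not measure the spread between sets. The estimated correlation also brings in the 3 residual degrees of freedom, so a call lost with it is not due to the correlation alone.

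The test was run first on simulated data. Counts were drawn for 8 such sums with 200 changed genes among 13847. Of 50 genes changed 2-, 4-, 8- and 16-fold, 18%, 64%, 82% and 96% were recovered, and 6 of 13647 unchanged genes were called. Changed genes were drawn only from those above a low mean expression, and every gene had the dispersion of the fitted trend. These shares therefore do not cover genes with few reads or with a wider spread between sets than the trend. For summed reads, both sides of a comparison were drawn as Poisson counts from the E10.5 Endo sum. The interval of the ratio held the true fold in 95.3% of 12394 genes. Such draws hold counting error only, so this checks the calculation and not the spread between cells or embryos. A list shifted by a log2 of 1 had a median of 1.00 at percentile 100, and 2 of 22 other lists lay outside the central 95% of random lists.

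Alternatives were DESeq2 1.42.0, its size factors within edgeR, no filter on low counts, no block, each sort set left out, the cells of disagreeing labels as a further set or added to either stage, the endothelial sort without the misspelt titles, no mitochondrial genes, and an estimated correlation. For summed reads they were TMM scaling, the mean of per-cell CPM, leaving out for each gene the cell with most of its reads in each group, and leaving out list members under 5 CPM. Both kinds were also run on cells thinned to 280000 reads, the 10th percentile of all cells rounded down, which left out 137 cells, and on the 1391 cells with at least 100000 reads, 1500 genes and at most 10% mitochondrial reads. After the data had been seen, 2 more were added. The first left out 83 erythroid-like cells with at least 1% of reads in 7 globin genes, and the second kept cells with reads of at least 10 of 20 pan-endothelial genes (fewer than 10 in the Mes gate). Shares of cells were recomputed with at least 5 reads and with thinned cells. Other scripts used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.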

Results

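Transcriptomes of 1457 single cells from the aorta-gonad-mesonephros (AGM) region of ICR mouse embryos were examined. The AGM is the embryonic site where blood stem cells bud from the wall of the dorsal aorta. Full-length cDNA was made by the Smart-seq2 method from cells sorted by flow cytometry into single wells. The sorts followed the endothelial-to-hematopoietic transition, in which hemogenic endothelium (HE) rounds up and forms intra-aortic hematopoietic clusters (IAHC). Endothelial cells (Endo) were sorted as CDH5+ cells without the reporter, KIT, CD41, CD45 or TER119. HE cells passed the same gate but carried a GFI1 or a RUNX1b reporter. Cells in transition (EHT) were positive for CDH5, KIT, CD41 and the GFI1 reporter, and IAHC cells carried the GFI1B reporter as well. A mesenchymal gate (Mes) took CDH5-negative cells with the RUNX1b reporter, and a separate set of sorts used angiotensin-converting enzyme (ACE) on the cell surface together with GFI1.

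The heterozygous Gfi1/Gfi1b line gave 74 Endo, 95 HE, 41 EHT and 42 IAHC cells at E10.5. At E11.5 it gave 16 Endo, 40 HE and 22 IAHC cells whose title and stage field both named that stage. Homozygous Gfi1/Gfi1b knockout (KO) embryos gave 42 HE cells at E10.5. The Runx1b line gave 53 Endo cells and 91 Mes cells of KO embryos, and its heterozygous HE and Mes cells made up 17.98% and 7.34% of all 1457 cells. A further 19.01% of all cells were HE cells of that line titled KO but with a heterozygous genotype field, so they are called titled KO throughout. The ACE sorts held 14 ACE− GFI1− cells and 39 ACE+ GFI1+ cells, and ACE+ GFI1− cells made up 7.96% of all cells. In 42 EHT, 41 Endo and 43 HE cells the title said E11.5 and the stage field E10.5, and these entered no comparison of the stages.

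Reads per cell ranged from 12 to 5652968 with a median of 598000, and the median cell had reads of 6576 genes. Median reads per cell lay between 421344 and 1149730 in the E10.5 groups, but reached 2777260 in Endo, 2173460 in HE and 3977380 in IAHC at E11.5. No label named an embryo, so each group counted as 1 sample and 13 comparisons had no replicate check. For these, values are reads of a gene summed over the cells of a group per 1000000 reads of that group (CPM). Among the 312 named differences the higher value rested on at least 404 reads, and its exact 95% Poisson interval reached at most 9.51% below and 10.2% above it. Reads carried no molecular identifiers, so intervals and detection limits cover counting error only. Sorts of the same gate from different lines at E10.5 also differed. The 95th percentile of the absolute log2 ratio was 0.97 to 1.77 between endothelial sorts and 1.52 to 1.94 between HE sorts.

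Runx1, the transcription factor required for blood formation, lies on chromosome 16 from 92601466 to 92826149 (GRCm38, minus strand, ENSMUSG00000022952). Its reads were found in 0 of 74 E10.5 Endo cells, which allows a share of up to 4.05%, but in 47.4% of HE cells (exact binomial interval 37% to 57.9%). All 41 EHT and all 42 IAHC cells had Runx1 reads, at 233.7 and 183.9 CPM against 61.4 CPM in HE. The repressor gene Gfi1 (chromosome 5, 107716657 to 107726036, minus strand, ENSMUSG00000029275) was at 55.2 CPM in HE, 136.5 CPM in EHT and 69.7 CPM in IAHC. Gfi1b (chromosome 2, 28609450 to 28621982, minus strand, ENSMUSG00000026815) was read in 43.9% of EHT cells and 92.9% of IAHC cells, as the gates select. Ptprc, which encodes CD45, was read in 19.5% of EHT and 57.1% of IAHC cells although the gates excluded CD45 on the surface.

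**Figure D1:**
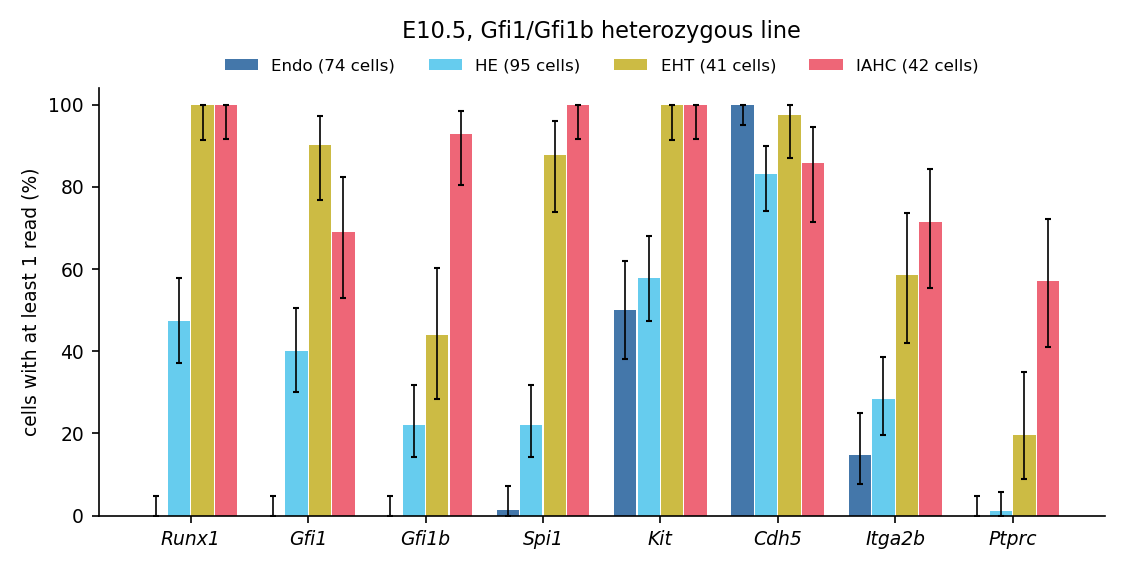
Share of E10.5 cells of the Gfi1/Gfi1b heterozygous line with at least 1 read of 8 gate and target genes in 4 sorts, in percent, with exact 95% binomial intervals as error bars and 74, 95, 41 and 42 cells. Runx1 was read in 0% of Endo cells, 47.4% of HE cells and 100% of EHT and IAHC cells.

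HE and endothelium were compared across 4 sort sets, the only comparison with replicates. Apelin and genes of the venous list fell in HE. Apln, the ligand of the apelin receptor, fell by 7.30 ± 1.04 on the log2 scale (standard error), from a mean of 87.6 to 0.857 CPM, with an adjusted p of 0.0452. Nrp2, a VEGF-C co-receptor of veins and lymphatics, fell by 5.25 ± 0.53 (adjusted p = 0.0193), and Kitl, the ligand of KIT, fell by 4.07 ± 0.32 from 99.02 to 5.98 CPM (adjusted p = 0.0123). The myeloid transcription factor gene Spi1 rose from 0.0233 to 25.3 CPM (log2 10.49 ± 1.12, adjusted p = 0.0220), and Gfi1, which gates some of these sorts, rose from 0.138 to 61.7 CPM (adjusted p = 0.0331). Fitted ratios of genes with few endothelial reads depend on the prior count and are no bounds.

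Other rises among the 24 genes taken by the naming rule were the embryonic globin genes Hba-x, Hbb-bh1 and Hbb-y, the beta-globin gene Hbb-bt and the red cell membrane gene Smim1. Beside them stood the cardiac actin gene Actc1 (0.0341 to 562 CPM), the mesenchymal homeobox gene Prrx1 (0.0353 to 31.6 CPM), Afap1l2, Nell1 and the stress-induced gene Nupr1. Further falls were Adgrg3, the multimerin gene Mmrn1, Ripply3, the podoplanin receptor gene Clec1b, the basement membrane collagen gene Col15a1, Nlrc3, the repressor gene Prdm1, Gchfr and the adaptor gene Dok4, the last by 3.17 ± 0.18 with an adjusted p of 0.0117. Of the gate genes, Runx1 was higher in all 4 sets (mean 1.01 to 51.1 CPM) but its adjusted p was 0.114. Neither Kit (102.8 and 124.7 CPM, adjusted p = 0.650) nor Cdh5 (710.3 and 1038 CPM, adjusted p = 0.291) nor Itga2b (3.88 and 20.9 CPM, adjusted p = 0.136) nor Ace (3.09 and 21.7 CPM, adjusted p = 0.287) nor Gfi1b (0.450 and 22.8 CPM, adjusted p = 0.218) passed.

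**Figure D2:**
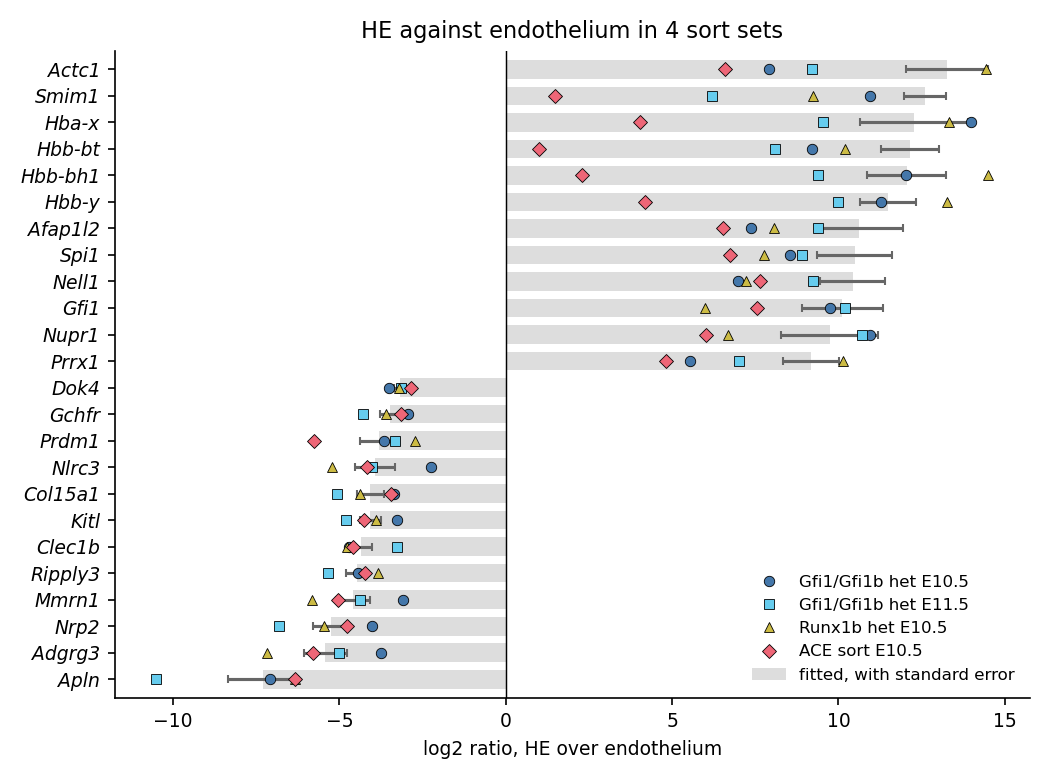
Log2 ratio of HE to endothelium for the 24 named genes in each of the 4 sort sets (points, after TMM scaling, with any sort under 3 reads of a gene set to 3 reads). Gray bars and whiskers give the fitted log2 fold change and its standard error, and fitted values lie beyond the points where endothelial sorts held few reads. All 12 falls lay below 0 and all 12 rises above 0 in each set, and the globin genes and Smim1 spread most between sets.

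By gene list, arterial genes rose, with 5 of 20 measured members past the threshold over all genes and 14 when adjusted over the list alone (median log2 ratio 1.77, adjusted p = 6.68e-07). They included Hey2, a Notch target of arteries (log2 5.15, 5.88 to 151.7 CPM), the gap junction gene Gja5 (3.69) and the Notch ligand gene Jag1 (2.35). Venous genes fell, with 2 of 11 members past the threshold and 6 adjusted over the list alone (median −2.75, adjusted p = 2.03e-05). This median was −4.46 without the E10.5 Gfi1/Gfi1b set, −4.23 without the Runx1b set and −4.24 with cells that had reads of at least 10 of 20 pan-endothelial genes. In the ACE set the HE sort differed from the endothelial sort by ACE as well as by GFI1. There the arterial list was higher and the venous list lower already in ACE+ GFI1− cells, and the arterial list differed little once GFI1 was added. That set therefore does not tie the arterial rise to GFI1, but both list calls stayed without it. Hematopoietic transcription factors rose in 5 of 20 measured members, or 11 adjusted over the list alone (median 3.07, adjusted p = 9.50e-08). The hematopoietic surface list rose (median 3.98, adjusted p = 2.58e-04) with 1 member up, the adhesion receptor gene Cd44 (log2 4.35), 1 down and 10 adjusted over the list alone, and its median was 2.64 with thinned cells. Glycolysis genes fell in 5 of 16 members, or 13 adjusted over the list alone (median −0.96, adjusted p = 4.32e-06), among them the pyruvate kinase gene Pkm, which fell by 1.70. Each of these 5 list calls was lost with an estimated correlation (adjusted p = 0.436, 0.429, 0.429, 0.429 and 0.429 with an estimated correlation, in the order given). The list p-values with the preset correlation do not measure the spread between sets.

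The replication, mitosis, ribosome biogenesis and oxidative phosphorylation lists fell in the test over all 4 sets, without any of their 80 members passing the threshold. Their medians were −0.78, −0.90, −0.61 and −0.40 with adjusted p of 4.95e-06, 4.68e-05, 5.05e-06 and 7.15e-05, and 10, 0, 5 and 0 members passed when adjusted over the list alone. With an estimated correlation their adjusted p = 0.447, 0.482, 0.442 and 0.447. The fall of mitosis genes was not shared by all sets. The mitosis median was −0.45 without the E11.5 set (adjusted p = 0.00573), and in the E10.5 Gfi1/Gfi1b set by itself it was 0.13, at percentile 100 of the random lists. The replication, ribosome biogenesis and oxidative phosphorylation medians of that set, −0.14, −0.18 and −0.35, lay among those of random lists (percentiles 88.4, 70.8 and 18.8). These percentiles count all cells, the erythroid-like cells of that HE sort among them, and so do not settle whether these 3 lists fell there. Lists of other cell types also rose in the HE sorts. The erythroid list had a median of 12.06 with 5 of 9 measured members up and 8 adjusted over the list alone (adjusted p = 8.66e-06, and adjusted p = 0.436 with an estimated correlation). Without erythroid-like cells its median was 2.67 with 0 of 7 members past the threshold and 2 adjusted over the list alone (adjusted p = 0.0320). With cells that had reads of at least 10 of 20 pan-endothelial genes it was 3.63 with 0 of 8 and 2. For the megakaryocyte list (median 3.99, 1 of 10 up, the von Willebrand factor gene Vwf, and 5 adjusted over the list alone) the adjusted p was 7.86e-04, for the mesenchyme list (median 4.48, 1 of 13 up, Prrx1, and 3 adjusted over the list alone) it was 0.0228, and for the sympathetic list (median 3.22, 0 of 5 up and 4 adjusted over the list alone) it was 0.00190. These 3 had adjusted p = 0.429, 0.447 and 0.429 with an estimated correlation. The megakaryocyte median was 2.38 without the block and 2.64 with the cells of conflicting stage labels as a further set, and the mesenchyme median 2.89 without the Runx1b set. The mesenchyme list summed to 5838 CPM in the Runx1b HE sort, where 50% of cells had fewer than 10 of 20 pan-endothelial genes, and to 200.7 to 339.9 CPM in the other HE sorts. Its call ended with cells of at least 10 such genes (adjusted p = 0.0824) and with the cells of conflicting stage labels as a further set (adjusted p = 0.0950).

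Notch signalling (median 0.93, 2 of 17 up, 6 adjusted over the list alone, adjusted p = 0.00789), the inflammatory list (1.02, 2 of 16 up, 3 adjusted over the list alone, adjusted p = 0.0480) and extracellular matrix (0.36, 3 of 18 up, 7 adjusted over the list alone, adjusted p = 0.0445) rose. With an estimated correlation they had adjusted p = 0.447, 0.447 and 0.499. The inflammatory and extracellular matrix calls also ended without the ACE set (adjusted p = 0.149 and 0.164), without the E11.5 set (0.0541 and 0.0532) and with the cells of conflicting stage labels as a further set (0.0991 and 0.1001), the former with thinned cells (0.0695) and the latter without the Runx1b set (0.0539). The extracellular matrix median was 0.71 without the filter on low counts. Their called members included the interferon-induced genes Ifitm1 and Ifitm3, the fibronectin gene Fn1 (446 to 3497 CPM), the fibrillin gene Fbn1 and the elastin gene Eln. Lists that did not pass were pan-endothelial (adjusted p = 0.949), niche ligands (0.949), adhesion and epithelial-mesenchymal genes (0.579), BMP and TGF-beta signalling (0.341), dissociation stress (0.167), macrophage (0.140), cyclin-dependent kinase inhibitors (0.101) and smooth muscle (median 1.95, adjusted p = 0.0688). The smooth muscle list passed, upward, without the filter on low counts (adjusted p = 0.00921), with thinned cells (0.0341), without erythroid-like cells (0.0321), without the misspelt titles (0.0311), with the cells of conflicting stage labels as a further set (0.0422), and without the E10.5 Gfi1/Gfi1b (0.0268), the E11.5 (0.0236) or the ACE set (0.0428), but not without the Runx1b set (0.240), with an estimated correlation (adjusted p = 0.593) or under the other 5 alternatives (0.0556 to 0.0690). The kinase inhibitor list passed, upward, without the filter (adjusted p = 0.0421) and without the ACE set (0.0457). The pan-endothelial median was 0.06 although the test pointed down, and the list passed upward with cells chosen by these same genes (median 0.32, adjusted p = 0.0463). In that list Robo4, a guidance receptor gene of vessels, fell by 1.87 and the sialomucin gene Emcn fell by 1.09.

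In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 1.40% of 14553 genes. Of these, 63.2% were higher and 75 genes lower in HE, and all but 2 had the same sign in all 4 sets. The gates differed between sets, and leaving out 1 set changed the count. Without the E10.5 Gfi1/Gfi1b set edgeR called 20 genes, without the E11.5 set 0.895% of genes, without the Runx1b set 3 and without the ACE set 0 (1977 genes at an unadjusted p under 0.05). DESeq2 called 2587 genes with all 4 sets, and edgeR without the sort set as a block called 442 (3.04%). With every cell thinned to the same number of reads 5.01% of genes were called, and with cells that had reads of at least 10 of 20 pan-endothelial genes 3.47%. Cells with at least 1% of reads in globin genes made up 16.8%, 11.8% and 5% of the cells of 3 of the HE sorts although the gate excluded TER119. Without them 1.64% of genes were called, with all but 20 of the calls above among them, and the globin genes were not.

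Within the Gfi1/Gfi1b heterozygous line at E10.5, the HE sort held more reads of blood transcription factors and of red cell genes than the Endo sort. Nearly all red cell reads lay in 16 erythroid-like cells, since the erythroid list summed to 147134 CPM in HE, 107.5 CPM in HE without these cells and 130.6 CPM in Endo. Beside Runx1 (at least 823-fold higher than the limit of 3 reads over all Endo cells) and Gfi1 (at least 739-fold), the largest values were Hba-x at 37508 against 2.69 CPM and Hbb-y at 70540 against 32.99 CPM. Higher in HE were also Nupr1 (127.5 and 0.0249 CPM), the kidney membrane protein gene Pdzk1ip1 (71.01 and 0 CPM), the potassium channel gene Kcnn4, the acid phosphatase gene Acp5 (164.6 and 3.21 CPM) and Ifitm1 (40.9 and 0.0746 CPM). Endo cells held the apelin receptor gene Aplnr at 792 CPM against 18.6 CPM in HE, the venous transcription factor gene Nr2f2 at 74.4 against 1.08 CPM, Apln at 62.1 against 0.395 CPM and the potassium channel subunit gene Kcne3 at 203.1 against 0 CPM. Gpr183, Lhx6 and Tmem255a were likewise lower in HE.

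The list of hematopoietic transcription factors had a median log2 ratio of 3.76, above all 10000 matched random lists, and 16 of 23 measured members were at least 2-fold higher. Among them Klf1 and Gata1, regulators of red cells, were at 191.8 and 75.5 CPM in HE. Lists of other cell types were higher in the same HE sort. The epithelial list had a median of 4.36 (6 of 6 measured members at least 2-fold higher, 78.9 against 5.42 CPM in sum), the mesenchyme list of 2.02 (11 of 20, percentile 99.95, 264.8 against 168.4 CPM in sum) and the sympathetic list of 1.90 (6 of 8, percentile 99.5, 377 against 141.7 CPM in sum). Without erythroid-like cells these medians were 4.76, 2.42 and 1.87. The median HE and Endo cells had reads of only 2 and 1 of the 24 mesenchyme genes, and the sums of that list differed less than its median. The arterial list had a median of 0.76 (9 of 20 members at least 2-fold higher, Gja5 at 778 against 160 CPM), the venous list of −2.34 (7 of 11 lower) and the glycolysis list of −0.96 (7 of 16 lower, Pkm at 458 against 1541 CPM). Cells with at least 1% globin reads numbered 16 of 95 in HE and 0 of 74 in Endo. Without them the transcription factor median was 2.22, and Gfi1b was at 9.06 in place of 52.1 CPM. The median gene had a log2 ratio of −0.21, and TMM scaling adds 0.17 to every ratio.

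From HE to EHT, genes of the myeloid lineage and of the hematopoietic cell surface were higher and endothelial genes lower. Mpo, the myeloperoxidase gene of granulocyte precursors, was at 123.7 CPM in EHT against 0.0146 CPM in HE (1 read), and Prtn3 at 63.6 against 0.863 CPM. The signalling genes Plek (36.4 and 0 CPM), Rac2 (41.2 and 0.366 CPM), Btk (26.3 and 0 CPM) and Fcer1g (60.99 and 1.13 CPM) were higher too, as was the chemokine gene Ccl9 (54.5 and 0 CPM). Kit, a gate gene, was at 607 against 112.1 CPM and Cdh5 at 398 against 692 CPM. Lower in EHT were the plasminogen activator gene Plat (0 and 52.02 CPM), the caveolin gene Cav1 (0.874 and 51.1 CPM), Dab2 (0.728 and 54.01 CPM) and Tmem100, a gene induced by BMP in arteries (8.01 and 237.1 CPM).

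The surface list had a median of 2.41, with 17 of 22 members at least 2-fold higher, and hematopoietic transcription factors 1.02, with 12 of 23 higher, among them Spi1 at 244.7 against 24.1 CPM and Myb at 170.7 against 28.2 CPM. Pan-endothelial genes had a median of −0.97, arterial genes −1.77, venous genes −2.92 and extracellular matrix −1.74, each below all 10000 random lists. Ribosome biogenesis genes had a median of 0.71 and glycolysis genes 0.67, with the hexokinase gene Hk2 at 99.4 against 24.2 CPM. Of the lists of other cell types, macrophage (median 1.62) and megakaryocyte genes (1.42) were higher in EHT, and mesenchyme (−1.78) and sympathetic genes (−1.98) lower. The globins, at most 22.2 CPM in EHT, led the lower genes because of the erythroid-like cells of the HE sort, and Car2, a carbonic anhydrase gene of red cells, was lower (31.03 and 997 CPM) but was higher in EHT by a log2 ratio of 1.58 without those cells. TMM scaling adds −0.26 to every ratio.

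From EHT to IAHC, arterial and Notch genes were lower and leukocyte genes higher. The arterial list had a median of −3.17 with 17 of 20 members at least 2-fold lower, among them Gja5 (1.70 against 76.4 CPM), the netrin receptor gene Unc5b (1.03 against 70.1 CPM) and the semaphorin receptor gene Nrp1 (13.4 against 270 CPM). Notch signalling had a median of −2.03 and pan-endothelial genes −1.06. Macrophage genes had a median of 1.22, megakaryocyte genes 0.50 and smooth muscle genes −1.52. The macrophage list summed to 679.8 against 372.8 CPM, and the median cell of both sorts had reads of only 3 of its 16 members. The surface list was higher by a median of 1.62, with Rac2 at 287 against 41.2 CPM, Tyrobp at 75.6 against 16.02 CPM, Ptprcap at 64.8 against 13.7 CPM and Ptprc at 85.4 against 27.7 CPM. Hematopoietic transcription factors differed little (median −0.05), with Gfi1b at 156.4 against 50.1 CPM and Gfi1 at 69.7 against 136.5 CPM. Also higher were the immunoglobulin heavy chain gene Ighm (44.6 and 2.14 CPM), Rgs18 (36.02 and 2.72 CPM) and Il18rap, and also lower Akr1c14 (0 and 81.9 CPM) and Tm4sf1 (0 and 46.2 CPM).

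Across the whole path, IAHC cells had fewer endothelial and more blood transcripts than Endo cells. Spi1 was at 313 against 0.0249 CPM (1 read), Ikzf1 at 184.5 against 0 CPM and Myb at 206.99 against 0.522 CPM, whereas Aplnr was at 0.277 against 792 CPM, the scavenger receptor gene Stab1 at 3.72 against 441 CPM and the stretch-activated channel gene Piezo2 at 0 against 183.2 CPM. List medians were −2.51 for pan-endothelial, −4.61 for arterial, −5.88 for venous and −3.03 for extracellular matrix genes, and 5.97 for the surface, 3.78 for the transcription factor, 4.82 for the macrophage and 3.04 for the megakaryocyte list. The dissociation stress list was lower by a median of −0.60, with Atf3 at 1.15 against 91.3 CPM. The epithelial list had a median of 4.46 over only 5 measured members, led by the keratin gene Krt18 (69.4 and 3.16 CPM).

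**Figure D3:**
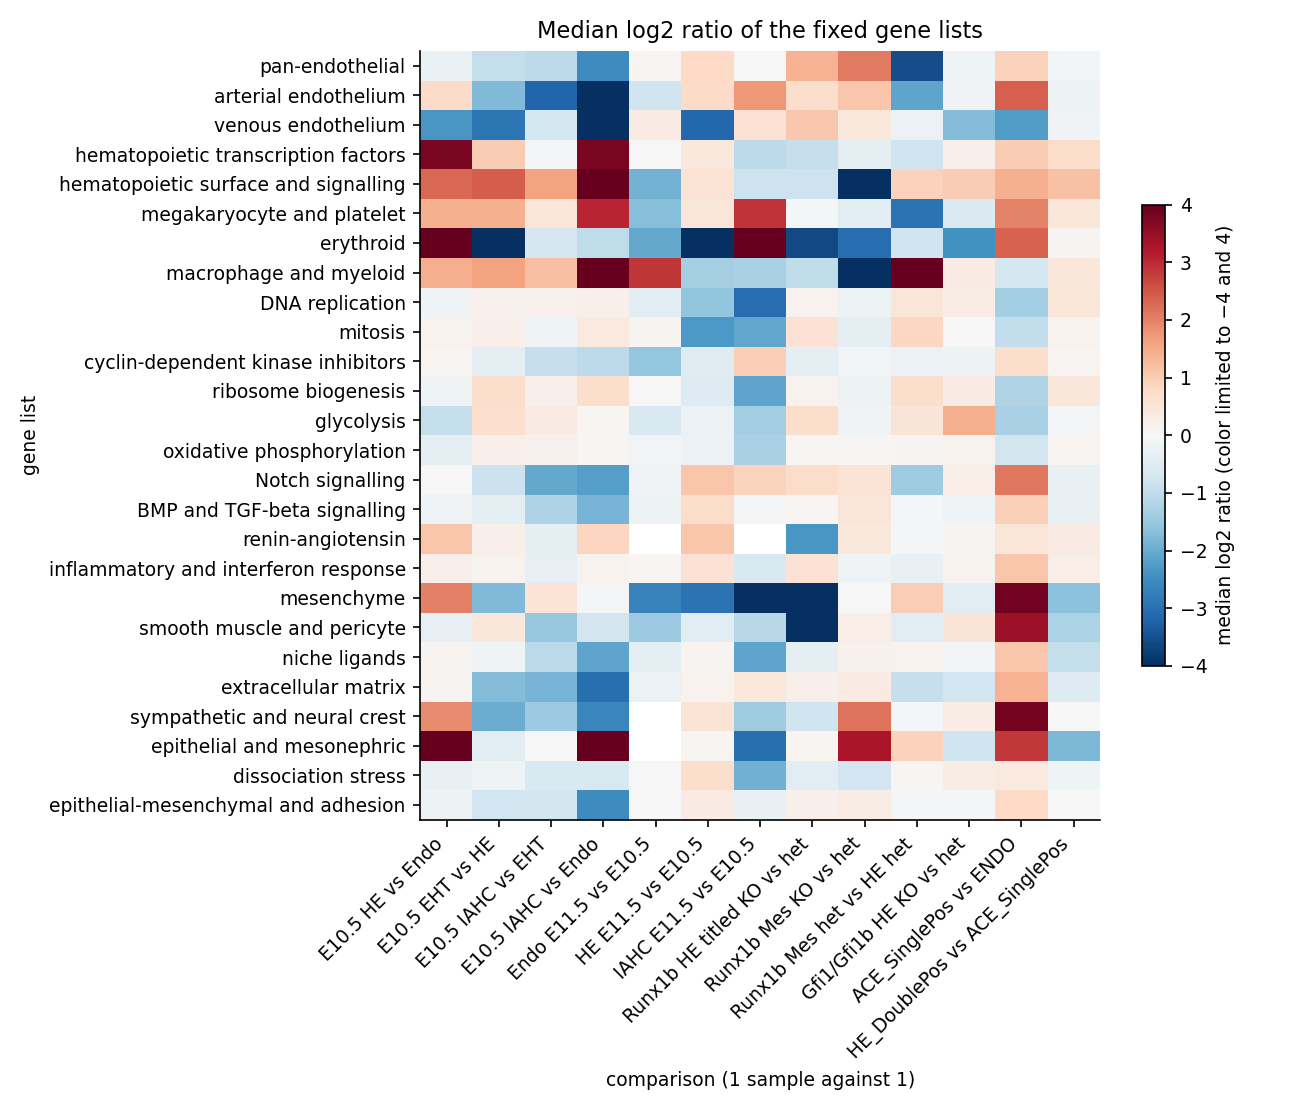
Median log2 ratio of the 26 fixed gene lists (lists down the side) in the 13 comparisons of 1 sample against 1 (across), as a color scale limited to −4 and 4, with lists under 5 measured members left blank. Venous genes were lower in HE than in Endo (−2.34) and in ACE+ GFI1− than in ACE− GFI1− cells (−2.24).

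Between E10.5 and E11.5, cell division genes were lower in the HE sort. Of 20 mitosis genes, 19 were at least 2-fold lower at E11.5 (median log2 ratio −2.29), among them the proliferation marker gene Mki67 at 41.8 against 455 CPM and the topoisomerase gene Top2a at 40.7 against 485 CPM. Of 20 DNA replication genes 17 were lower (median −1.56), with the thymidylate synthase gene Tyms at 29.4 against 295 CPM. Notch signalling (median 1.10, Hey2 at 291 against 73.2 CPM), pan-endothelial (0.80) and arterial genes (0.76) were higher, and mesenchyme genes lower by the median (−2.95, 12 of 19 members). Reads of the mesenchyme list summed to 200.7 against 264.8 CPM, a far smaller difference. The median cell of both sorts had reads of 2 of its 24 members, so that median rests on members with few reads. Single genes included the phosphate transporter gene Slc34a2 (77.05 and 0.293 CPM) and the cartilage matrix gene Chad (95.1 and 4.33 CPM) on the higher side, and the zinc transporter gene Slc39a8 (1.55 and 152.3 CPM), Atf3 (0.0698 and 47.5 CPM), Prc1 and Clspn on the lower.

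Globins were lower too (Hba-x 480 and 37508 CPM), with 2 of 40 erythroid-like cells at E11.5 and 16 of 95 at E10.5. Without these cells the arterial median was 0.36, the pan-endothelial median 0.40 and the mitosis median −2.33, while Hbb-y, lower at 1754 against 70540 CPM, had a log2 ratio of 1.98. Reads of Xist, expressed in female cells, were found in 2 of 40 E11.5 HE cells and 46.3% of E10.5 HE cells, so the 2 sorts differed in the sex of their embryos. TMM scaling adds −0.22 to every ratio.

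In Endo cells the arterial list was lower at E11.5 (median −0.80, below all 10000 random lists), led by Gja4 (40.3 and 368 CPM) and the chemokine receptor gene Cxcr4 (0.355 and 25.5 CPM). Kinase inhibitor genes (−1.54) and glycolysis genes (−0.61, Slc2a1 at 269.4 against 912 CPM) were lower, and the scavenger receptor gene Cd36 was higher (117.3 and 4.43 CPM), as were Slc34a2 (42.5 and 0.423 CPM) and the macrophage list (median 2.85, 4 of 7 members). Only 16 E11.5 Endo cells were sorted, and the arterial median was −0.41 with thinned cells, −2.13 without the largest cell of each gene and 0.15 when the cells of conflicting stage labels counted as E11.5.

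IAHC cells at E11.5 could be compared only in part, since 14 of 22 had at least 1% of reads in globin genes, against 0 of 42 at E10.5, and Hbb-y alone took 300756 CPM. TMM scaling adds 1.10 to every ratio. With and without these cells, arterial genes were higher (median 1.73 with and 3.27 without) and DNA replication genes lower (−3.04 with and −1.68 without). The surface list was at −0.84 with and 0.79 without them. In the 8 E11.5 cells left, reads of the megakaryocyte list summed to 8225 CPM, against 525 CPM at E10.5, and of the pan-endothelial list to 4976 against 2754 CPM.

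In the Runx1b line, the titled KO cells of the HE gate had fewer Runx1 reads than the heterozygous cells. Runx1 was read in 6.86% of titled KO cells (exact interval 4.18% to 10.504%, 1.47 CPM) and in 26.3% of heterozygous cells (21.1% to 32.1%, 17.8 CPM). Reads over the whole locus were counted, and the part replaced by the reporter is not given in the sources used here. Transcripts of vessel-wall cells were lower by far in the titled KO cells. The smooth muscle list had a median log2 ratio of −5.07 and the mesenchyme list of −4.26, with 22 of 24 members at least 2-fold lower, among them Col1a1 (13.2 and 1854 CPM), the enteric actin gene Actg2 (1.28 and 572 CPM), the pericyte genes Rgs5 (5.43 and 599 CPM) and Cspg4 (0.625 and 133.7 CPM), and Pdgfrb (2.09 and 186.3 CPM). Pan-endothelial genes were higher by a median of 1.38 and Cdh5 was at 2139 against 822 CPM. Higher were also the collagen receptor gene Itga2 (35.2 and 3.40 CPM), Tmem255a (147.4 and 19.3 CPM), Mmrn1 (35.03 and 4.50 CPM) and Igfbp3 (992 and 156.3 CPM), and the glycolysis list (median 0.70, Slc2a1 at 756 against 179.01 CPM).

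The make-up of the heterozygous sort differed from the other. At least 10 of the 20 pan-endothelial genes were read in 50% of its cells and in 97.8% of titled KO cells, and only 4 cells lay between 7 and 12 genes. The cells below 10 genes included 30 with at least 1% globin reads, and 80.9% of them had reads of the smooth muscle actin gene Acta2. Runx1 was read in 41.98% of the cells below 10 genes and in 10.7% of the cells above (5.97% to 17.3%, 4.84 CPM), against 6.27% of titled KO cells chosen likewise (3.70% to 9.85%, 1.15 CPM), so these intervals of the share overlapped. Among cells with at least 10 of these genes, the pan-endothelial median was 0.30 and Cdh5 was at 2168 against 1762 CPM. In these cells the mesenchyme median was −1.11, the smooth muscle median −0.68, and the dissociation stress median −0.86 with Fos at 44.3 against 469 CPM and Fosb at 3.13 against 59.9 CPM, while Aplnr was at 113.4 against 16.2 CPM. The transcription factor list had a median of −0.91 over all cells, 0.11 without the erythroid-like cells and −0.51 with the endothelial choice. Xist was read in 81.3% of heterozygous and 65.7% of titled KO cells.

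**Figure D4:**
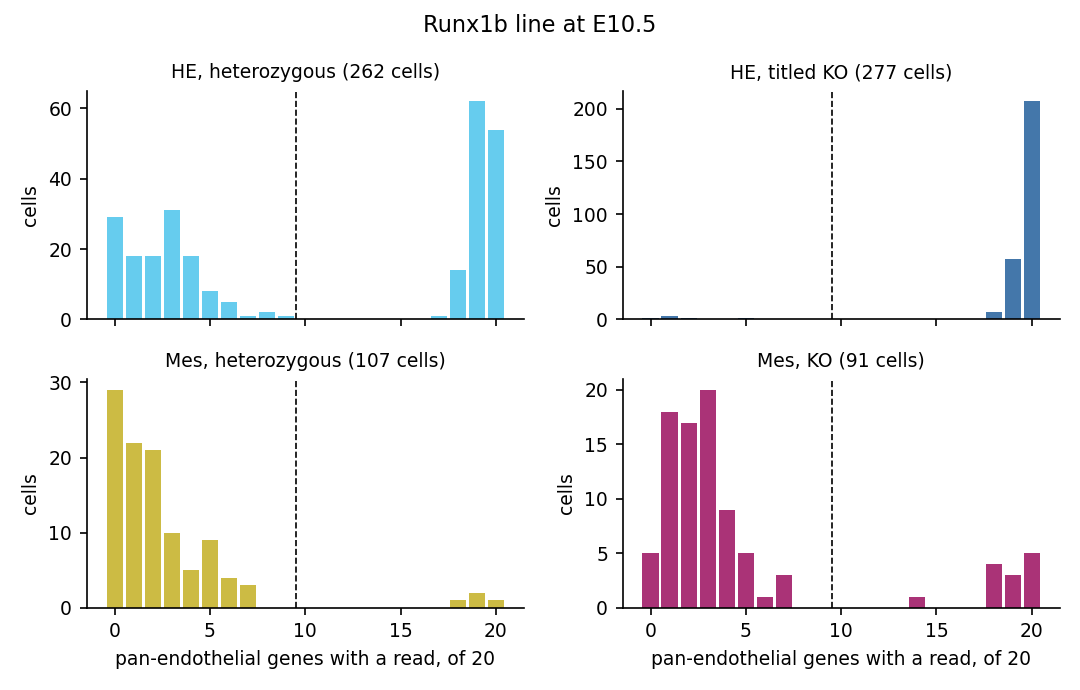
Number of cells by how many of 20 pan-endothelial genes had at least 1 read, in the HE and Mes sorts of the Runx1b line. In the heterozygous HE sort 50% of cells had fewer than 10 genes, and in the titled KO HE sort 6 cells had.

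In the Mes gate, Runx1 was read in 47.3% of KO cells (36.7% to 58%, 20.1 CPM) and 39.3% of heterozygous cells (29.95% to 49.2%, 35.3 CPM), so these reads did not part the genotypes. Macrophage genes were read almost only in the heterozygous sort. C1qb was at 111.7 CPM there and at 0 CPM in KO cells, the list median was −8.21, and Ptprc was read in 12.1% of heterozygous cells and 0 of 91 KO cells, which allows a share of up to 3.30%. Epithelial genes were higher in KO cells (median 3.27, 11 of 13 members, Cldn6 at 36.5 against 0.446 CPM and Krt18 at 74.6 against 7.76 CPM), as were sympathetic and neural crest genes (2.16, Ret at 30.6 against 2.14 CPM) and the transcription factor gene Isl1 (78.8 and 16.1 CPM). Lower in KO cells were the metallothionein gene Mt1 (16.2 and 204.2 CPM), the lipase gene Lpl (8.70 and 68.1 CPM) and the dissociation stress list (−0.78, Zfp36 at 20.1 against 112.9 CPM), and the mesenchyme list itself had a median of 0.00.

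Pan-endothelial genes were also higher in KO cells (median 2.08, Plvap at 426 against 60.3 CPM), with at least 10 of the 20 genes read in 13 of 91 KO and 4 heterozygous cells (3.74%). Globins were lower (Hba-x 1096 and 12989 CPM), with 1 and 10 erythroid-like cells. Xist was read in 49.5% of KO cells (38.8% to 60.1%) and 82.2% of heterozygous cells (73.7% to 88.96%), so the Mes sorts differed in sex make-up. Kit was at 110 against 25.8 CPM by summed reads, but the mean of per-cell values gave a log2 ratio of −2.87. Among cells with fewer than 10 of the 20 genes, Kit was read in 52.6% of KO and 20.4% of heterozygous cells. Among the 13 and 4 cells above, the shares were 38.5% and 50%. The shallowest KO and heterozygous cells held 22 and 14 reads, so single reads can weigh much in such a mean. Whether they did was not tested.

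Against the heterozygous HE sort, heterozygous Mes cells were lower in endothelial genes, as the gate sets (pan-endothelial median −3.56, Pecam1 at 20.3 against 540 CPM, Vwf at 40.9 against 965 CPM). Mes cells were higher in mesenchyme genes (median 0.97), among them the Wilms tumor gene Wt1 (63.2 and 1.52 CPM), in the signalling genes Ptn (194.2 and 16.5 CPM) and Wnt5a (48 and 6.24 CPM), in the chondrogenic factor gene Sox9 (93.02 and 10.1 CPM) and in Igfbp5 (274.4 and 19.2 CPM). Macrophage (7.84) and mitosis genes (0.82) were higher too, and megakaryocyte genes lower (−2.95). Where only HE cells with at least 10 pan-endothelial genes and Mes cells with fewer were counted, the mesenchyme median was 4.59.

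The Gfi1/Gfi1b KO cells of the HE gate had reads of both targeted genes. Gfi1 was at 218.9 CPM in KO and 55.2 CPM in heterozygous cells, and Gfi1b at 91.6 and 52.1 CPM, or 0.510 and 9.06 CPM without erythroid-like cells. The reporters sit in these genes, and the part replaced is not given in the sources used here, so these reads check nothing. KO cells were higher in glycolysis genes, with a median log2 ratio of 1.47 above all 10000 random lists and 12 of 16 members at least 2-fold higher. Gapdh was at 1266 against 294 CPM, the phosphoglycerate kinase gene Pgk1 at 544 against 126.3 CPM and the phosphofructokinase gene Pfkp at 37.6 against 5.44 CPM. The glucose transporter gene Slc2a3 (356 and 46.8 CPM) and the genes Bnip3 (28.3 and 3.57 CPM) and Ankrd37 (39.2 and 6.42 CPM), known to be induced by low oxygen, were also higher, as were Fggy, Pde4b and Cav1 (274.5 and 51.1 CPM).

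Lower in KO cells were the BMP regulator gene Bmper (0 and 27.1 CPM), the channel gene Trpc6 (0 and 24.3 CPM), Eln (0.785 and 34.2 CPM), Cxcr4 (1.91 and 33.1 CPM), Dkk2, Wnt11, Isl1 and the extracellular matrix list (median −0.78). The surface list was higher (1.01), with Rac2 at 23.7 against 0.366 CPM and Kit at 260.9 against 112.1 CPM, and Runx1 was at 98.5 against 61.4 CPM. Hematopoietic transcription factors had a median of 0.21, and −0.15 without erythroid-like cells, which were 4 of 42 KO and 16 of 95 heterozygous cells. The erythroid list had a median of −2.41, and −2.16 without these cells. Xist was read in 2.38% of KO cells and 46.3% of heterozygous cells, so the KO cells were almost all male. TMM scaling adds −0.13 to every ratio.

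In the ACE sorts, Ace itself (chromosome 11, 105967945 to 105989964, plus strand, ENSMUSG00000020681) was read in 21.4% of ACE− GFI1− cells (exact interval 4.66% to 50.8%, 0.343 CPM), 61.2% of ACE+ GFI1− cells (51.7% to 70.1%, 52.9 CPM) and 84.6% of ACE+ GFI1+ cells (69.5% to 94.1%, 27.8 CPM). The ACE+ GFI1− cells carried arterial genes. Against ACE− GFI1− cells the arterial list had a median of 2.38 with 18 of 20 members at least 2-fold higher, among them Hey2 (131.9 and 0.960 CPM), the kinase gene Bmx (127.8 and 2.54 CPM) and Gja5 (2916 and 60.2 CPM). Notch signalling (2.11) and extracellular matrix (1.40, Fn1 at 4317 against 379 CPM) were higher, as were the wall genes Acta2 (452 and 3.36 CPM) and Fbln2 (323 and 0.823 CPM), the receptor gene Ret (100 and 0.960 CPM) with the sympathetic list (3.82), and the epithelial list (2.84, Krt18 at 101.2 against 3.57 CPM). The mesenchyme list had a median of 3.85, the smooth muscle list of 3.44 and the megakaryocyte list of 1.97.

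Venous genes were lower (−2.24), with Aplnr at 19.8 against 1958 CPM, Nrp2 at 8.73 against 250 CPM and Apln at 4.79 against 197.9 CPM. So were DNA replication (−1.36) and glycolysis genes (−1.31, Ldha at 951 against 3158 CPM). The renin-angiotensin list, to which Ace belongs, had a median of 0.48 over 7 measured members. ACE− GFI1− cells numbered 14 at a median of 1149730 reads, against 89 cells that passed the cell filter and 27 that did not, at a median of 504028 reads.

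With the GFI1 reporter added, blood factor genes were higher. Against ACE+ GFI1− cells, ACE+ GFI1+ cells had Runx1 at 56.03 against 1.19 CPM, read in 38.5% and 5.17% of cells, Spi1 at 22.2 against 2.46 CPM, Gfi1, the gate gene, at 104.1 against 0.772 CPM and the adhesion receptor gene Adgrg1 at 235.3 against 33.1 CPM. The ubiquitin ligase gene Neurl3 (347 and 46.5 CPM), the osteopontin gene Spp1 (74.6 and 5.35 CPM) and Kit (143.5 and 34.2 CPM) were higher as well. Transcription factors had a median of 0.74 with 8 of 20 members at least 2-fold higher, the surface list 1.17 and DNA replication 0.49. Lower were Acta2 (58.4 and 452 CPM), Kitl (4.35 and 33.4 CPM), Tgfb2 (8.56 and 51.03 CPM), Tmem255a (3.86 and 89.1 CPM) and the niche ligand (−0.96), mesenchyme (−1.66) and smooth muscle lists (−1.26). The renin-angiotensin median was 0.34, and the arterial list differed little by summed reads (−0.21) and by the mean of per-cell values (0.08). TMM scaling adds −0.11 to every ratio.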

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

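The values in this part come from comparisons chosen beforehand, and only the values without erythroid-like cells were chosen after the result was seen. Among the 30 genes examined across the 4 sort sets for a set far from the others, Clec1b stood apart in the E11.5 Gfi1/Gfi1b set. Its log2 ratio of HE to endothelium was −3.27 there and −4.58 to −4.77 in the other sets. The gap took 0.873 of the whole range, above the critical value that chance passes in about 1 of 20 such groups, so 1 of 30 genes is no more than chance gives.

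Lists moved in opposite directions between gates from E10.5 to E11.5. The arterial list had a median log2 ratio of −0.80 in Endo cells, but 0.76 in HE cells and 1.73 in IAHC cells. The dissociation stress list had a median of 0.72 in HE cells and −1.92 in IAHC cells. Without erythroid-like cells the arterial medians were −0.80, 0.36 and 3.27 and the stress medians 0.40 and −0.79. At E11.5, 14 of 22 IAHC cells were erythroid-like, so the IAHC medians without them rest on few cells. With all cells, TMM scaling adds 1.10 to every IAHC ratio. Each gate had 1 sample per stage, so the differences between gates were not tested, and the Endo value rests on 16 cells at E11.5 and was 0.15 when cells of conflicting stage labels counted as E11.5.

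Endo cells titled E11.5 with a stage field of E10.5, which entered no main comparison, held more reads of some other lists than the Endo cells of either stage. The megakaryocyte list summed to 1493 CPM, against 238.2 and 170.2 CPM in the other Endo sorts. The sympathetic list summed to 363.8 CPM, against 141.7 and 67.95 CPM, and the epithelial list to 36.49 CPM, against 14.8 and 5.42 CPM. Vwf, a member of the megakaryocyte list, is also a gene of endothelium, and the median such cell had reads of 1 of the 12 megakaryocyte genes.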

How the results depend on the processing

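The gene lists, the rule for named genes, the tests and most alternatives were fixed before the data were examined, and the alternatives without erythroid-like cells and with cells kept by pan-endothelial genes were chosen after the result was seen. Of 43 named genes tested between HE and endothelium, none turned direction, and 74.3% of 641 values kept their side of the threshold. Without 1 sort set, 37 (ACE), 31 (Gfi1/Gfi1b E10.5), 36 (Runx1b) or 14 (Gfi1/Gfi1b E11.5) of them did not, in part because fewer sets were left. For 16 tested lists, 89.1% of the values kept direction and side, and 16 of the 26 losses came with an estimated correlation, which left 0 lists past the threshold. For genes compared between single samples, 98.9% of 1181 values kept their sign (13 changed it) and 53.9% stayed within counting error, and 322 of those that moved were smaller. For lists, 97.6% of 584 medians kept their sign (14 changed it), 64.4% moved by less than 1 SD of the random lists, and 100 of the others were larger. Of 38 shares of cells, 35 stayed within their interval. Depth limits genes and list members near 3 reads and, with thinned cells, leaves out the shallowest cells. Unless stated, the cause was not tested.

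The share of genes called between HE and endothelium was 1.40%, and 0% to 0.895% without 1 sort set (fewer sets). It was 3.04% with no replicate block, 5.01% with thinned cells, 3.47% with cells kept by pan-endothelial genes and 17.8% with DESeq2. Leaving out the block changed no call of the 16 lists, but 37 of the main gene calls were lost. Among the 43 named genes it ended the calls of Hbb-bh1, Hbb-y, Pkm and Ifitm1 and added that of Runx1 (adjusted p = 0.0272 with edgeR).

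List medians (log2) below belong to hematopoietic transcription factors (TF) or the list named, with the main value first. TMM scaling shifts all genes, and gave 3.93 for TF in HE against Endo (main 3.76), 0.76 in EHT against HE (1.02), 0.077 in Gfi1/Gfi1b KO (0.21), 0.53 for arterial genes in HE at E11.5 (0.76) and 0.26 for surface genes in IAHC at E11.5 (−0.84). The mean of per-cell CPM gave TF 0.83 in EHT against HE, 0.084 in Gfi1/Gfi1b KO and 0.96 in ACE+ GFI1+ cells (0.74), arterial 0.55 in HE at E11.5 and 0.0765 in ACE+ GFI1+ cells (−0.21), pan-endothelial −1.20 in IAHC against EHT (−1.06) and −2.68 against Endo (−2.51), and Kit −2.87 in Mes KO. Thinned cells gave TF 0.78 in EHT against HE, pan-endothelial −1.20 in IAHC against EHT and arterial −0.41 in Endo at E11.5 (−0.80). Without each gene's largest cell, TF was 4.66 in HE against Endo and −0.11 in Gfi1/Gfi1b KO, pan-endothelial −1.22 in IAHC against EHT, arterial −2.13 in Endo at E11.5 and 3.56 in ACE+ GFI1− cells (2.38), surface −1.63 in IAHC at E11.5 and mesenchyme 0.71 in Mes against HE (0.97). Without members under 5 CPM, TF was 3.91 in HE against Endo and −0.12 in titled KO (−0.91). Cells of conflicting stage labels made the arterial median of Endo 0.15 when added to E11.5 and −1.59 when added to E10.5.

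Without erythroid-like cells, TF was 2.22 in HE against Endo, 1.17 in EHT against HE, 0.11 in titled KO and −0.15 in Gfi1/Gfi1b KO, arterial 0.36 in HE and surface 0.79 in IAHC at E11.5, and mesenchyme −0.14 in Mes KO (0.00). The ratio of Car2 in EHT against HE became 1.58 and of Hbb-y in HE at E11.5 1.98. With cells kept by pan-endothelial genes the same 9 values were 1.78, 1.15, −0.51, −0.047, 0.35, 0.63, 0.20, 1.56 and 2.24, and mesenchyme in Mes against HE was 4.59.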

Other observations

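The tests chosen only after the result was seen are those on cells without endothelial genes and on cells without erythroid-like cells, and the counts of cells with reads of both sex markers were also looked up afterwards. The HE cells whose title said E11.5 and whose stage field said E10.5 were nearer in division genes to E11.5 than to E10.5 HE cells. Against E10.5 their median log2 ratio was −1.72 for the mitosis list and −1.31 for DNA replication, and against E11.5 it was 0.48 and 0.15. Their arterial median was 0.76 against E10.5 and 0.05 against E11.5. The Endo cells with the same conflict had DNA replication medians of −1.13 against E10.5 and −0.75 against E11.5, and arterial medians of 1.05 and 2.48, so they lay outside both stages.

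EHT cells with this conflict resembled E10.5 EHT cells in Runx1 (194.04 and 233.7 CPM) and Spi1 (270.3 and 244.7 CPM). Ptprc was read in 73.8% of them (exact interval 57.96% to 86.1%, 173.6 CPM) and in 19.5% of E10.5 EHT cells (8.82% to 34.9%, 27.7 CPM). The macrophage colony-stimulating factor receptor gene Csf1r was at 81.6 against 2.62 CPM, read in 21.4% and 7.32% of cells. Gfi1b was lower, at 20.7 against 50.1 CPM. Reads of both Xist and a Y-linked gene were found in 9 of 39 ACE+ GFI1+ cells and 3 of 14 ACE− GFI1− cells, but in only 2 of the ACE+ GFI1− cells, a sort that held 7.96% of all cells. In the Gfi1/Gfi1b line they were found in 1 of 95 E10.5 HE cells, 3 of 16 E11.5 Endo cells and 6 of 41 Endo cells of conflicting stage labels, so such cells did not set the ACE sorts apart from that line. The other 13 groups had 0 to 5 such cells each. Whether these wells held RNA of more than 1 cell was not tested.

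Mesenchyme and smooth muscle genes were lower in the titled KO HE cells of the Runx1b line, by a median of −4.49 over both lists. The median was −4.63 with thinned cells. Thinning keeps the expected CPM of each cell, so this argues only against the weight of deeply read cells. Other effects of depth stay open. Cells without endothelial genes in the heterozygous sort are a candidate source, since 95.7% of that sort's reads of the lists lay in cells with fewer than 10 of 20 pan-endothelial genes, where Acta2 stood at 10626 CPM and Col1a1 at 3408 CPM. A gate on CDH5 would remove such cells, and Cdh5 was read in 6.11% of them. Why the 2 sorts differed in such cells, by genotype, litter or sorting, was not tested, and a wrong title or genotype field stays open.

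Glycolysis genes were higher in Gfi1/Gfi1b KO than in heterozygous HE cells, by a median of 1.47. The median was 1.58 between 37 KO and 46 heterozygous cells with Y-linked and no Xist reads, which argues against sex as the whole cause. It was 1.26 without erythroid-like cells, which argues against those cells likewise. With thinned cells it was 1.41, which argues only against the weight of deeply read cells, since thinning keeps expected CPM. A candidate explanation that stays open is the knockout itself, and so are litter, sorting day and the time cells spent at low oxygen, none of which was tested.

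Mitosis and DNA replication genes were lower in HE cells at E11.5 than at E10.5, by a median of −2.03. The median was −2.19 between 29 and 46 cells with Y-linked and no Xist reads and −2.06 without erythroid-like cells. This argues against sex and erythroid-like cells as the whole cause. With thinned cells it was −2.12, which argues only against the weight of deeply read cells, since thinning keeps expected CPM. Stage, as the design names it, may explain the difference, but it stays untested beside litter and sorting day.

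For the test of HE against endothelium, the 8 sums of cells were also split in other ways with the same block. Of the 8 splits that parted the sorts of all 4 sets, 1, the real one, gave as many genes, and the highest other gave 0. These splits are too few for a share under 0.05.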
